A study of Drosophila melanogaster with 18 samples.

How the data were processed

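Fragments protected from micrococcal nuclease (MNase), an enzyme that cuts the DNA between nucleosomes, were sequenced from total nuclei of Drosophila melanogaster S2 cells, an embryonic cell line. Of the 18 samples in the series, 3 libraries of total nuclei were analysed here, each the 1 library of its group. One came from cells given DRB for 10 min, one from cells heat shocked for 15 min at 37 °C, and one from cells given both treatments. The other 15 samples, which include the untreated total nuclei, the low-salt and high-salt fractions, the RNA polymerase II fractions and the nucleosome turnover samples, were not analysed here.

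Reads were aligned with Novoalign, per the submitters' processing notes. Its version, the genome build, the mapping filters and the treatment of repeated fragments are not given in the sources used here. Libraries were made with a modified Illumina protocol without size selection on a gel, per the labels' protocols. The deposited files list the chromosome arm, start and end of each fragment, with no other value. Identical fragments occur many times in the deposited lists, so repeats had been kept. The lists hold fragments on 6 arms (2L, 2R, 3L, 3R, 4 and X), and everything below refers to those. Starts were read as 0-based and are printed 1-based. A gene table of Drosophila Release 6 was at hand, but 1483 of its 17684 genes on these arms end past the last fragment of their arm in the files, 800 of them on 2R. The files therefore use another build, and no fragment was assigned to a gene. The planned measurements of gene bodies, gene lists, promoters and start sites were not run for that reason. The Release 6 table was used only for the arms of the genes in a list of heat shock genes.

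All counts of fragments were made here from the deposited lists. A fragment was assigned to a bin by its midpoint. Length classes were set before the data were examined as short (20 to 75 bp), intermediate (76 to 119 bp), nucleosomal (120 to 180 bp) and long (over 180 bp). Shares carry Wilson 95% intervals and ratios of 2 counts exact (Clopper-Pearson) 95% intervals. They cover counting error only, and fragments copied by PCR are not independent molecules. With 1 library per group there is no replicate error, no test between treatments was made and no p-value is given. Each comparison compares the libraries named.

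Log2 ratios carried a pseudocount of 0.5. For bins of 1 kb, fragments of every length were scaled to the library totals, bins with at least 50 fragments summed over the 3 libraries were kept, and an absolute log2 ratio of at least 0.5 was counted. The spread that counting alone gives was simulated by splitting each bin's pooled count at random in the proportions of the library totals. In place of named genes, the rule for files without a matching annotation took the 5 bins with the highest and the 5 with the lowest ratio of each of the 3 comparisons. The windows of 5 kb for short fragments were added after seeing the data, as were their threshold, an absolute log2 ratio of at least 1, and their scaling to the median window. They first needed 60 short fragments summed over the 3 libraries. That gave 22 windows higher in both heat-shocked libraries, where unchanged libraries drawn at random gave up to 11, and 10 with identical fragments counted once, where they gave up to 17. The minimum was then raised to 200, which gave 8 windows and 8. The smaller minimum is kept as an alternative. The draws of unchanged libraries and the splits of the DRB library numbered 100 each. Blocks of 1 Mb with at least 100000 nucleosomal fragments were compared relative to all nucleosomal fragments.

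Nucleosome spacing was the first peak, between 120 and 260 bp, of the autocorrelation of nucleosomal midpoints. At most 20 midpoints per base were counted, the curve was smoothed over 21 bp, and a peak had to be the highest point within 15 bp. This rule was set after the plain maximum had fallen on the lower edge of the range. Sites rich in short fragments, also added after seeing the data, were the 5000 bins of 100 bp with the most distinct short fragments, at least 2 kb apart. Bins whose surroundings held over 5 times the mean density, or less than the mean divided by 5, were left out. A profile of nucleosomal fragments over 1 kb to each side of such sites was made first and replaced by the level within 100 bp. Levels are relative to the library's own genome mean of the same length class. Every other distinct fragment, in order of position, was used to choose the sites and the rest to measure them, with intervals from 1000 bootstrap draws of sites. Both parts therefore hold nearly the same count at a site, and the measured levels keep the bias of the choice.

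The scripts used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pyarrow 21.0.0 and matplotlib 3.10.9. They were tested on simulated data. For the comparison of DRB and heat shock against DRB, over 120138 bins of 1 kb, 80.9% of bins changed 1.5-fold and 100% of those changed 2-fold were counted, against 0.159% of unchanged bins. For short fragments, over 12775 windows of 5 kb, windows raised 4-fold in both heat-shocked libraries were found in 100% of cases, those raised 2-fold in 27.4%, those raised 1.5-fold in 1.59% and unchanged ones in 0%. Simulated arrays spaced at 160, 170 and 190 bp gave those values. Alternatives covered the class limits, the fragment minimum, the bin size, the scaling, nucleosomal fragments alone and identical fragments counted once.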

Results

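Nuclei of S2 cells were digested with MNase after 3 treatments, and the protected fragments were sequenced from both ends. DRB inhibits the kinase CDK9, which RNA polymerase II needs to leave its pause near promoters. Heat shock at 37 °C turns on the heat shock genes. The series asks how heat shock changes active chromatin, and DRB separates effects that need elongating polymerase. The DRB library held 38729455 fragments, the library of DRB and heat shock 45319618, and the heat shock library 42956232. Identical copies made up 45.4%, 43.4% and 42.8% of them, which left 21134007, 25660598 and 24549580 distinct fragments. There were no replicates, and an untreated library was not analysed here. The genome build is not given in the sources used here, so positions are those of the files and no gene is assigned to them.

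Nucleosome-sized DNA dominated all 3 libraries, and the heat shock library had the longest fragments. Nucleosomal fragments made up 55.2% of the DRB library, 56.7% of the library with both treatments and 56.1% of the heat shock library. The most common length was 147, 150 and 147 bp in the same order, and the median 154, 154 and 158 bp. Short fragments, which can come from DNA covered by other proteins or from nucleosomes cut inside, made up 6.30% with DRB, 6.73% with both treatments and 5.41% with heat shock. On X the short share went from 8.21% with DRB to 9.58% with both treatments and 9.88% with heat shock, the only arm with a higher share with heat shock than with DRB. Without the 5 kb window X from 20250001, left out after its values were seen, it was 5.78%, 6.40% and 4.91%. Intermediate fragments gave 14.8%, 14.7% and 11.8%. Long fragments gave 23.7%, 21.8% and 26.7%. The widest 95% interval of these shares spanned 0.0314 percentage points. The heat shock library had the longer median fragment on each of the 6 arms, by 3 to 6 bp over DRB.

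**Figure D1:**
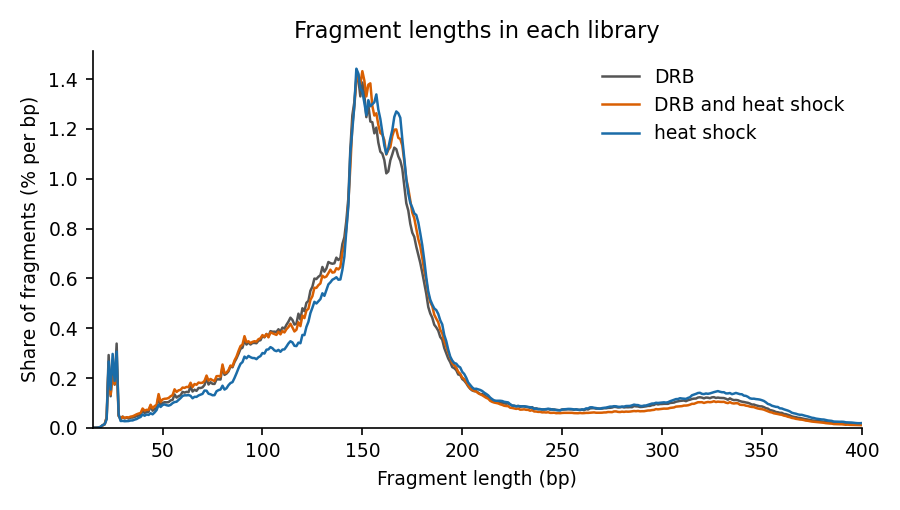
Share of fragments (percent per bp, vertical axis) at each fragment length (bp, horizontal axis), with 1 line per library. The main peak lies at 147 to 150 bp in all 3 libraries, and the heat shock line runs below the others between 30 and 140 bp.

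With DRB in both libraries, the heat-shocked one had more short fragments at a few places on arms 3R and 3L. The highest of 12704 windows of 5 kb was 3R from 7780001 to 7785000, which held 49 short fragments with DRB and 450 with DRB and heat shock, a log2 ratio of 2.77 (counting interval 2.35 to 3.24). The adjoining window, from 7785001 to 7790000, went from 46 to 211 fragments (log2 1.77, 1.31 to 2.27). Next came 3L from 9375001 to 9380000 with 52 and 205 fragments (1.55, 1.12 to 2.03), 3R from 8325001 to 8330000 with 69 and 266 (1.52, 1.14 to 1.93) and 3R from 19880001 to 19885000 with 71 and 263 (1.46, 1.09 to 1.87). In all, 11 windows lay at least 1 higher and 5 at least 1 lower on the log2 scale, against 0 and 0 in counts split at random. Scaled to all fragments of every length, which moves the median window to 0.19, the split was 42 higher and 1 lower. The lowest windows were 2R from 950001 to 955000 (284 and 159 fragments, log2 -1.25) and 3L from 1395001 to 1400000 (2050 and 1220, log2 -1.17). They held only 59 and 57, and 106 and 126, distinct fragments. With identical fragments counted once 0 windows were lower, but only 4375 windows then reached the minimum, and with a minimum of 60 there were 15.

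Heat shock alone against DRB alone had some of the same places at the top. The window 3R from 7780001 to 7785000 held 426 short fragments in the heat shock library, a log2 ratio to DRB of 3.18 (2.77 to 3.65). The adjoining window held 290 (2.72, 2.28 to 3.21) and 3R from 19880001 to 19885000 held 331 (2.29, 1.92 to 2.69). The others of the 5 highest were 2L from 19435001 to 19440000 (331 and 1923 fragments, 2.61) and 3R from 24265001 to 24270000 (2617 and 9569, 1.95), but these held 104 and 93, and 220 and 211, distinct fragments. The window 3L from 9375001 to 9380000, named above, held 191 (1.94). The lowest window was 3R from 480001 to 485000 (808 and 224, log2 -1.77), with 63 and 36 distinct fragments. This pair of libraries also differed over the genome as a whole. The SD of the log2 ratio over windows was 0.44, against 0.22 from counting alone, and 77 windows were higher and 204 lower. With identical fragments counted once, which leaves 4375 windows, 11 were higher and 13 lower, and with a minimum of 60 fragments 89 and 274. Scaled to all fragments the counts were 23 and 612, because the median window then lay at -0.23.

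The 5 kb windows, their minimum of 200 fragments and their threshold were chosen after the data were examined. Short fragments were at least 1 higher on the log2 scale in both heat-shocked libraries over DRB in 8 windows, which form 5 regions. Lower by at least 1 in both were 2 windows, 3L from 1395001 to 1400000 (2050, 1220 and 967 short fragments with DRB, both treatments and heat shock) and 2R from 950001 to 955000 (284, 159 and 134), where the draws gave a mean of 0. Identical fragments counted once gave 0 lower in both, or 3 with a minimum of 60, where the draws gave up to 6. Of the 8 higher windows 7 lie on 3R and 1 on 3L. Besides those named, they are 3R from 8290001 to 8295000 (98, 340 and 327 short fragments with DRB, both treatments and heat shock), from 8330001 to 8335000 (90, 318 and 320) and from 8335001 to 8340000 (72, 238 and 253). All 8 passed with identical fragments counted once. Both comparisons use the same DRB library, and 100 draws of unchanged libraries gave at most 1 such window, with a mean of 0.02. These draws hold counting error only and treat repeated copies as independent. Such draws had SDs over windows of 0.21 with both treatments and 0.22 with heat shock over DRB. The libraries themselves had 0.28 and 0.44. A minimum of 60 fragments, used first, gave 22 windows where the draws gave up to 11, and 10 with identical fragments counted once where the draws gave up to 17, so it was raised. The minimum of 200 was chosen with those draws in view, so the few windows they give at it are no independent support. Independent lists of these lengths would share 0.0667 windows. When the DRB fragments were split at random and each part served 1 comparison, 8 to 12 windows passed. Part of the excess may still come from the shared library, whose covariance of log2 ratios was 0.0649 against 0.0248 in the draws.

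**Figure D2:**
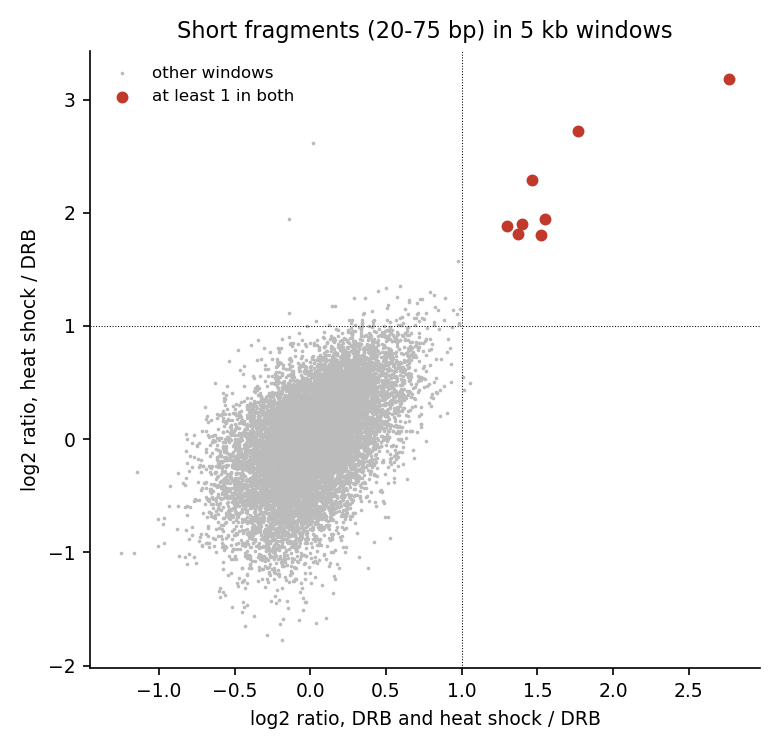
Log2 ratio of short fragments in 12704 windows of 5 kb, DRB and heat shock over DRB (horizontal axis) and heat shock over DRB (vertical axis), scaled to the median window. Each point is 1 window, dotted lines mark 1, and the 8 red windows are at least 1 in both, the highest at 2.77 and 3.18.

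Nucleosomal fragments ran the other way in most of these windows. Their median log2 ratio over the 8 windows was -0.41 with DRB and heat shock over DRB and -0.28 with heat shock over DRB, lower in 8 and 7 of the 8. The window 3R from 19880001 to 19885000 fell from 919 nucleosomal fragments with DRB to 690 with both treatments (log2 -0.69, -0.83 to -0.54) and held 818 with heat shock (-0.37, -0.51 to -0.23). The window 3R from 7780001 to 7785000 held 668, 515 and 506 (-0.65 and -0.60). In 3 windows the interval of heat shock over DRB spanned 0. In 3R from 8290001 to 8295000 it was -0.06 (-0.19 to 0.06), and in 3R from 8330001 to 8335000 -0.13 (-0.28 to 0.02). In 3R from 8325001 to 8330000, 752, 833 and 896 fragments with DRB, both treatments and heat shock gave -0.13 (-0.27 to 0.02) for both treatments over DRB and 0.05 (-0.09 to 0.19). Within the regions, the rise was uneven. In the bin 3R from 7781001 to 7782000 the DRB library held 12, the library with both treatments 203 and the heat shock library 195. In the bin 3R from 8332001 to 8333000 the counts were 5, 130 and 123. Nucleosomal fragments in the bin 3R from 7787001 to 7788000 numbered 331 with DRB, 213 with both treatments and 144 with heat shock. These 1 kb bins were chosen after their values were seen.

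**Figure D3:**
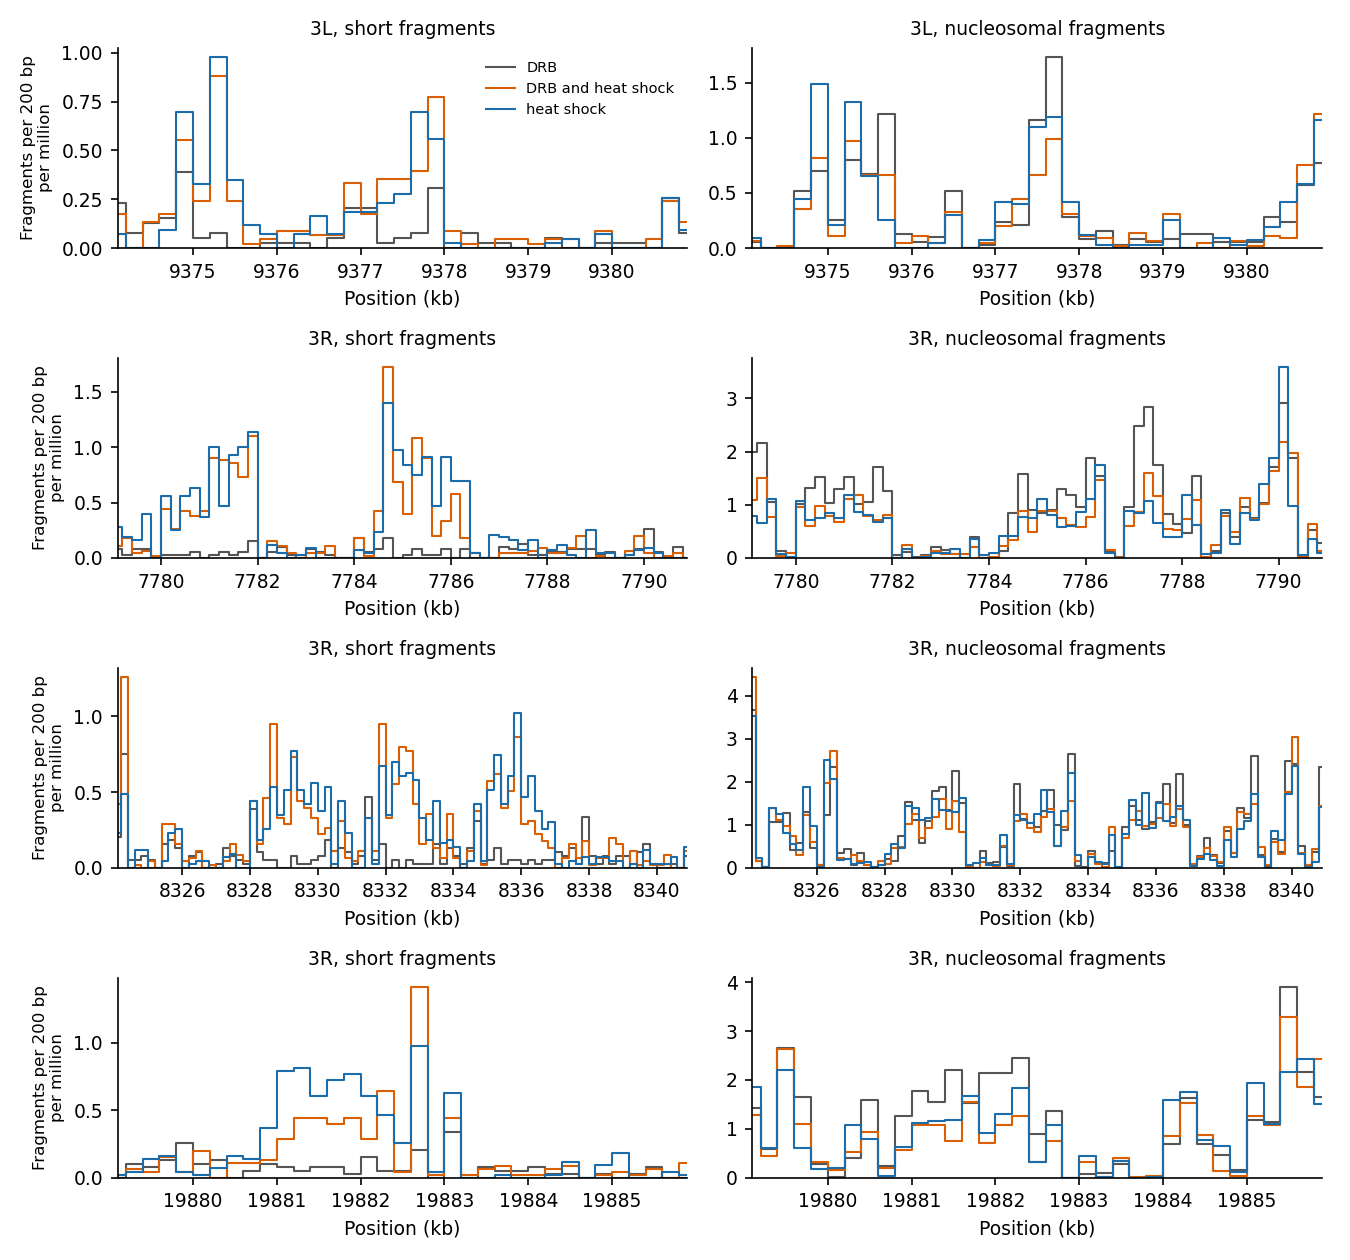
Fragments per 200 bp, scaled to the library total (vertical axis) along 4 of the 5 regions (position in kb, horizontal axis), short fragments on the left and nucleosomal ones on the right, 1 line per library. On 3R from 7781001 the heat-shocked libraries rise where the DRB line stays near 0, as in the bin with 12, 203 and 195 short fragments.

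With heat shock in both libraries, those with and without DRB were compared in the same windows, which were chosen for a difference of both heat-shocked libraries from DRB. The library with both treatments held 450 short fragments against 426 with heat shock in 3R from 7780001 to 7785000, 205 against 191 in 3L from 9375001 to 9380000, and 263 against 331 in 3R from 19880001 to 19885000. Scaled to the median window, the 8 ratios ran from -0.95 to -0.29. Scaled to all fragments they ran from -0.54 to 0.13, with a median of -0.05, and 3R from 7780001, 3L from 9375001 and 3R from 8325001 turned to 0.0017, 0.02 and 0.13. The furthest below 0 under both scalings was 3R from 7785001 to 7790000 (211 against 290 fragments, -0.95 and -0.54), followed by 3R from 19880001 to 19885000 (-0.83 and -0.41). Within the latter, the bin from 19881001 to 19882000 held 91 short fragments with DRB and heat shock and 159 with heat shock (log2 -1.30, -1.69 to -0.92), while the bin from 19882001 to 19883000 held 109 and 101 (-0.39, -0.79 to 0.02). Scaled to all fragments these bins lay at -0.88 and 0.03. Over the genome, 99 windows were higher and 26 lower in the library with both treatments, and 988 and 2 when scaled to all fragments, where the median window lay at 0.42. With identical fragments counted once, 3 were higher and 1 lower, but only 4375 windows then reached the minimum, and with a minimum of 60 the counts were 180 and 34. The 5 highest windows were 2L from 17185001 (115 short fragments with both treatments and 25 with heat shock, log2 1.68, 1.07 to 2.39), 2L from 685001 (126 and 28, 1.65), 3R from 480001 (949 and 224, 1.59), 4 from 360001 (123 and 30, 1.52) and 4 from 640001 (134 and 33, 1.51). Distinct fragments gave 1.40, 1.01, 0.40, 1.03 and 1.38, so the excess at 3R from 480001 lay mostly in repeated copies. The lowest window, 2L from 19435001 to 19440000, held 448 short fragments with both treatments and 1923 with heat shock, but 113 and 93 distinct ones.

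Fragments of every length in 1 kb bins were compared with and without heat shock when DRB was present. Over 120138 bins the SD of the log2 ratio was 0.20 against 0.14 from counting alone, and with identical fragments counted once 0.18 against 0.18. Of these bins 951 were at least 0.5 higher and 1143 lower, and 193 and 176 in the simulated counts. Identical fragments counted once gave 566 and 958, while nucleosomal fragments alone, with an SD of 0.28, gave 4544 higher and 3962 lower. Both settings leave fewer fragments per bin, which widens counting error. How many bins counting alone would give was not simulated for them, so these counts cannot be set against 193 and 176. The 5 highest bins were 3L from 9098001 (35 fragments with DRB, 105 with both treatments, log2 1.34, 0.79 to 1.95), X from 12065001 (35 and 101, 1.29), X from 13071001 (24 and 65, 1.19), X from 1449001 (35 and 92, 1.15) and X from 11177001 (24 and 61, 1.10). The 5 lowest were 2L from 627001 (50 and 21, -1.46, -2.29 to -0.72), 2L from 12467001 (65 and 31, -1.28), X from 83001 (70 and 36, -1.18), X from 11254001 (126 and 69, -1.09) and 2L from 8672001 (140 and 77, -1.09).

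The heat shock library stood apart from both others in the same bins. Against it, the library with both treatments had an SD of 0.24 (0.13 from counting), with 3565 bins higher and 1491 lower. The heat shock library against DRB had an SD of 0.27 (0.14 from counting), with 2812 higher and 5518 lower. Counting identical fragments once gave 3004 higher and 387 lower in the first, and 1154 higher and 5309 lower in the second, with SDs of 0.21 and 0.25. Nucleosomal fragments alone turned the balance of both comparisons, with 4176 bins higher and 5727 lower for both treatments over heat shock and 9168 higher and 6276 lower for heat shock over DRB. What counting alone would give was not simulated for them. The bin 3R from 484001 held 866 fragments with DRB, 987 with both treatments and 259 with heat shock, the highest ratio of both treatments over heat shock at 1.85 (1.65 to 2.06). It was followed by X from 36001 (25 and 7, 1.69), X from 51001 (34 and 10, 1.64), X from 5296001 (55 and 17, 1.59) and X from 6014001 (116 and 37, 1.56). Lowest in that comparison were 2L from 19438001 (746 and 2237, -1.66), 3R from 24267001 (3565 and 10044, -1.57), X from 4616001 (47 and 97, -1.11), X from 10685001 (36 and 72, -1.07) and X from 9666001 (475 and 935, -1.05). The bins 2L from 19438001, 3R from 24267001 and X from 9666001 held 280 and 250, 480 and 513, and 73 and 54 distinct fragments, so their excess lay in repeated copies. The bin 3R from 484001 held 67 and 44, a log2 ratio of 0.54 with identical fragments counted once. With nucleosomal fragments alone, X from 36001 lay at 0.27 and X from 5296001 at 0.56.

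For heat shock over DRB, the bins 2L from 19438001 (640 and 2237 fragments, log2 1.66) and 3R from 24267001 (2949 and 10044, 1.62) were again at the end of the list, but they lay at -0.16 and 0.08 with identical fragments counted once. They were followed by 2R from 3497001 (13 and 43, 1.54), X from 8971001 (16 and 47, 1.38) and 2L from 4086001 (65 and 182, 1.33, 0.92 to 1.77). Lowest were X from 36001 (32 and 7, -2.26), 3L from 3795001 (25 and 7, -1.91), X from 51001 (35 and 10, -1.91), 3R from 484001 (866 and 259, -1.89) and X from 12018001 (650 and 202, -1.83, -2.07 to -1.61). With nucleosomal fragments alone these 5 lay at -1.45, -0.96, -1.11, -0.95 and -1.35. The bin X from 12018001 held 408 fragments with both treatments, between the values of the others. The bin 3R from 484001 lay at -0.86 with identical fragments counted once.

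At a coarser scale most blocks held like shares of the nucleosomal fragments in the 3 libraries. Of 122 blocks of 1 Mb, 2 on X lay beyond 0.1 on the log2 scale against DRB, and the others ran from -0.06 to 0.06 with both treatments and from -0.07 to 0.07 with heat shock. The block X from 21000001 to 22000000 lay at -0.21 with both treatments and -0.57 with heat shock. One window of 5 kb in it, from 21830001, held 646192, 629165 and 404920 of its nucleosomal fragments with DRB, both treatments and heat shock. Without that window, which was left out after its values were seen, the block lay at -0.0025 and -0.06. The block X from 9000001 to 10000000 lay at -0.14 and -0.17. X held 13.9% of all fragments with DRB, 13.5% with both treatments and 13.3% with heat shock, and chromosome 4 held 1.30%, 1.28% and 1.24%. Without the window X from 21830001, X held 12.27%, 12.19% and 12.38%, so the fall with heat shock did not remain, and that with both treatments was smaller. With identical fragments counted once, X held 12.67%, 12.47% and 12.28%, a fall in both. No 95% interval of an arm share spanned more than 0.0269 percentage points.

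On arms other than 4, the distance between neighbouring nucleosomes differed by no more than the spread between arms. The autocorrelation of nucleosomal midpoints peaked at 178 bp in all 3 libraries. On single arms other than 4 the peak lay between 176 and 179 bp with DRB and with both treatments and between 176 and 180 bp with heat shock. Arm 4 gave 178 bp with DRB, but 128 and 130 bp with both treatments and heat shock. Identical fragments counted once gave 184, 184 and 129 bp on arm 4. The peaks at 128 to 130 bp lie below the most common fragment length, 147 to 150 bp. They were therefore not read as a distance between neighbouring nucleosomes. A second peak lay at 357, 353 and 353 bp.

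**Figure D4:**
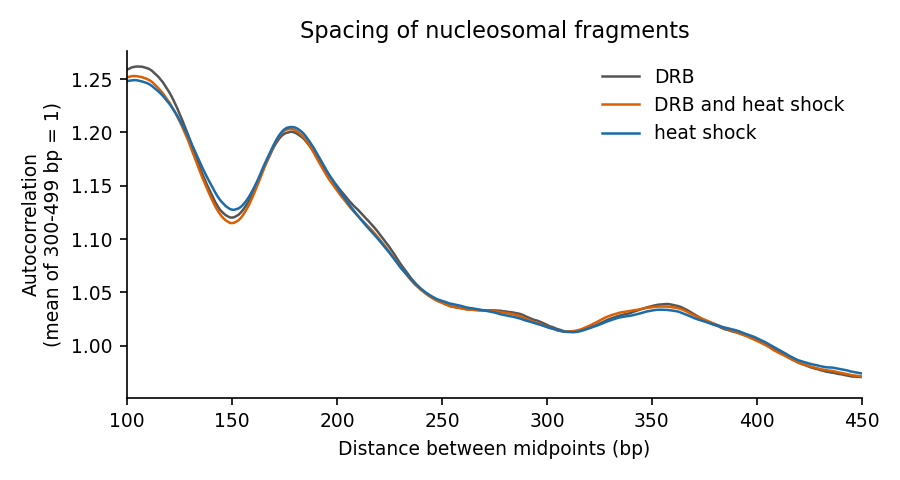
Autocorrelation of nucleosomal midpoints (vertical axis, relative to its mean at larger distances) against the distance between midpoints (bp, horizontal axis), with 1 line per library. The lines of the 3 libraries share a peak at 178 bp.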

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

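The alternatives for the 5 kb windows, counting identical fragments once in the 1 kb bins, those for named bins, and leaving out a window on X or 3L, were chosen after seeing the data; the others were set before. Shares and spacings below are given for DRB, both treatments and heat shock in that order, and the cause of a shift was not tested except where the setting itself makes it. No paired analysis was possible because each group has 1 library. The gene body, gene list, promoter and start site alternatives were not run, and limiting the shares to the main arms moves nothing, since the files hold no other. All 8 named windows were again higher in both heat-shocked libraries in each alternative with 5 kb windows except fragments of 20 to 60 bp, which kept 7.

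With identical fragments counted once, short fragments made up 6.05, 6.65 and 4.50%, intermediate 14.0, 14.0 and 11.6%, nucleosomal 51.2, 52.5 and 53.4% and long 28.7, 26.8 and 30.5%. X then held 12.7, 12.5 and 12.3% and chromosome 4 1.01, 0.984 and 1.01%. Without the 5 kb window X from 21830001, X held 12.3, 12.2 and 12.4%, so its fall with heat shock did not remain, and the 1 Mb block around it moved from -0.21, 0.36 and -0.57 to -0.0025, 0.05 and -0.06 for both treatments against DRB, the same against heat shock, and heat shock against DRB. The short share on X moved to 5.78, 6.40 and 4.91% without X from 20250001. On 3L it moved from 7.60, 7.37 and 5.59% to 5.35, 5.93 and 4.30% without 3L from 22780001, which turned both treatments from below DRB to above it. Limits of 20 to 60 bp gave short shares of 3.86, 4.03 and 3.43%, and limits of 140 to 160 bp nucleosomal shares of 24.5, 25.2 and 25.003%. Narrower limits take fewer fragments by construction. Of nucleosomal fragments alone, X held 14.3, 13.6 and 12.9% and chromosome 4 1.26, 1.21 and 1.21%. Spacing with fragments of 140 to 160 bp was 167, 167 and 168 bp, and counting identical fragments once gave 179 bp in all 3. It moved the peak of arm 4 to 184, 184 and 129 bp, the last too short to be read as a spacing.

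The values for 1 kb bins follow as DRB and heat shock against DRB, the same against heat shock, and heat shock against DRB. Bins of 5 kb gave SDs of 0.092, 0.12 and 0.14, with 0, 40 and 13 higher and 11, 6 and 136 lower. Nucleosomal fragments alone gave SDs of 0.28, 0.29 and 0.34, with 4544, 4176 and 9168 higher and 3962, 5727 and 6276 lower, which turns the balance of all 3 comparisons. These values rest on fewer fragments per bin, and the share due to counting error was not simulated. Identical fragments counted once gave SDs of 0.18, 0.21 and 0.25, with 566 and 1154 higher in the first and last and 387 lower in the second. The minimum of 200 fragments moved none of these by more than its limit. Among the 25 named bins, 15 of 60 values moved beyond their interval and kept their sign. With nucleosomal fragments alone, X from 36001 fell to 0.27 and X from 5296001 to 0.56 for both treatments against heat shock; with identical fragments counted once, 3R from 484001 lay at -0.86 for heat shock against DRB. The bin 2L from 19438001 reversed with identical fragments counted once, to 0.10 for both treatments against heat shock and -0.16 for heat shock against DRB, and X from 9666001 to 0.37.

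For short-fragment windows in the same order, identical fragments counted once left 0 lower in both heat-shocked libraries, 0 lower in the first, 3 higher and 1 lower in the second, and 11 higher and 13 lower in the third, with fewer windows tested. Limits of 20 to 60 bp gave 4 lower in both heat-shocked libraries, 7 higher in the first, 30 and 13 in the second and 28 and 108 in the third. Limits of 31 to 75 bp gave 0 lower in both, 0 lower in the first and 17 lower in the second. A minimum of 60 short fragments gave 22 windows higher and 4 lower in both heat-shocked libraries, with 50 and 36, 308 and 110, and 238 and 513 higher and lower. The same minimum with identical fragments counted once gave 10 higher in both, 20 and 15 in the first, 180 and 34 in the second and 89 and 274 in the third. Scaled to all short fragments, 14 were higher in both, with 22 and 3 in the first and 176 and 9 in the second. Scaled to all fragments of every length, 1 was lower in both, and the counts were 42 and 1, 988 and 2, and 23 and 612. Windows of 2 kb gave 17 higher and 6 lower in both, and 21 and 8 in the first. For both treatments against heat shock, the sign changed when scaled to all fragments of every length in 3R from 7780001 (0.0017), 3L from 9375001 (0.025) and 3R from 8325001 (0.13), and with 20 to 60 bp in 3L from 9375001 (0.078). Depth limits single windows: 1 of the 3 counts lay under 100 in all 8.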

Other observations

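All tests reported in this part were chosen after the results were seen. Of the 8 windows of 5 kb with the most fragments, 3 changed their share of the library by 1.76 times or more between the libraries, and the other 5 by at most 1.07 times. The window X from 21830001 to 21835000 held 698222 fragments with DRB, 676987 with both treatments and 439411 with heat shock, or 1.80%, 1.49% and 1.02% of the library, with a median length of 148, 150 and 148 bp. The window X from 20250001 to 20255000 went the other way, with 0.362%, 0.462% and 0.697%. Its fragments had a median length of 24 to 25 bp, and 968 distinct ones accounted for the 209509 found with both treatments. The window 3L from 22780001 to 22785000, also of fragments with a median of 25 bp, fell from 204905 with DRB to 154920 and 129010. Of the other 5, 3L from 23105001 to 23110000, with a median of 168 to 169 bp, kept 0.505%, 0.479% and 0.512%.

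At sites chosen for short fragments, their level relative to each library's own mean was highest in the heat shock library. At the 5000 sites with the most distinct short fragments, chosen after seeing the data, the fragments not used to choose them lay at 7.32 times the genome mean with DRB (7.18 to 7.47), 7.46 times with both treatments (7.34 to 7.59) and 9.91 times with heat shock (9.73 to 10.1, intervals over sites). With repeated fragments kept the levels were 7.36, 7.71 and 8.80. Each level is relative to the library's own short fragments. Those made up 6.05% of distinct fragments with DRB, 6.65% with both treatments and 4.50% with heat shock. A higher level therefore need not mean a larger share of the library at these sites. Fragments alternated in order of position between choosing and measuring, so both parts hold nearly the same count at a site. The levels thus keep the bias of the choice, and its size in each library was not measured. Nucleosomal fragments at these sites stood at 1.59, 1.56 and 1.62 times the genome mean. These levels were not set against the surroundings of each site. Whether the sites were poor in nucleosomes relative to their surroundings was therefore not tested.

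The rise of short fragments at the 8 windows on 3R and 3L is not explained by repeated copies, since with identical fragments counted once the median of the smaller log2 ratio was 1.40. A rise at every length is argued against by nucleosomal fragments (medians -0.41 and -0.28), which covers their class only. From DRB to heat shock, fragments of all lengths together rose in each window by more than the library totals. In 3R from 7780001 they went from 1277 to 1790, while short fragments went from 49 to 426 and nucleosomal ones from 668 to 506. Fragments of other lengths thus rose too, there and in each of the other windows. The rise with heat shock was therefore not limited to short fragments. With both treatments, fragments of all lengths together rose by more than the library totals in most windows. They did not in 3R from 7785001 (1832 and 2050) and 3R from 19880001 (1683 and 1818). An even shift of lengths over the library was set against the median of all windows. Scaled to all fragments, that median was 0.19 with both treatments over DRB and -0.23 with heat shock over DRB (SD 0.28 and 0.44). The 8 windows lay at 1.49 or more and 1.58 or more. They were picked for lying at least 1 above the median window, so this comparison could not have come out otherwise and does not decide. A shift limited to some places is not excluded either. Heat shock and any difference between single libraries remain open, and as a hypothesis the places may be loci of heat shock genes. All 4 loci, counting regions under 100 kb apart once, lie on 3L or 3R. The Release 6 table puts there the 17 genes found of the 20 on the list, and the others have no arm. However, those arms hold 51.7% of the windows, so chance gives 0.0715. With 4 loci that is the lowest value the test could give, and it lies above the limit of 0.05. With all 5 regions counted it would be 0.0370, under the limit. The joining was chosen after that count was seen, so the test does not decide.

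The longer fragments of the heat shock library (median 4 bp over DRB) were not seen when heat shock was combined with DRB, where the median differed from DRB by 0 bp. An effect of heat shock with or without DRB stays open, since the extent of MNase digestion in the library with both treatments could offset it. The shift was present on all 6 arms, which a weaker MNase digestion of that library would give. With 1 library per group, digestion and the treatments cannot be told apart.

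Along the named windows, the ratio of short fragments with both treatments to those with heat shock was uneven. Over 25 bins of 1 kb its SD was 0.47 on the log2 scale, above 0.35, the upper end of the central 95% of 10000 simulated draws. Their mean was 0.25 and their highest 0.48. Counting error alone thus gave so wide a spread in few draws. It was not excluded by the rule used, which asked for a value above every draw. With identical fragments counted once, 21 bins gave an SD of 0.336 against an upper end of 0.343, with fewer bins and fragments. Repeated copies may therefore account for part of the unevenness, and an effect of DRB on parts of these regions stays untested.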
